A study of Mus musculus with 48 samples.

How the data were processed

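Single mouse embryos at the 2-cell stage, 24 labelled WT and 24 labelled K49A, were sequenced one embryo per well with Smart-seq2, a method that copies whole polyadenylated transcripts from very small amounts of RNA. K49A stands in the series title for a substitution of 1 amino acid in protamine 1, the protein that packs DNA in the sperm head. The labels give the collection window as 26 to 28 hours after fertilization and the strain as C57BL6 for all embryos. They do not say which parent carried the substitution, which embryos shared a father or litter, or what the word "dot" means in 3 of the K49A titles. Each embryo is 1 individual and was counted as 1 replicate, and p-values measure the spread between these embryos, some of which can share a parent.

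Per the submitters' processing notes, the tools were cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3, with builds named GRCm38 and mm10. The main table holds expected counts per gene, estimated counts as deposited by the authors, over 55426 genes. All values were whole numbers, and they were rounded before use, which changed none. The 5 entries that name transgenes summed to 0 counts and were left out. A smaller deposited table of 32403 genes and the deposited count files of the single embryos held the same expected counts for those genes. The deposited TPM table of the authors served only as an alternative for the scores. A deposited file named for FPKM was identical to the TPM table and was not used here. The release of the gene annotation behind the counts is not given in the sources used here. RSEM, named in the notes without its role, divides reads among near-identical genes, so counts of the Zscan4, Tcl1b, Hba-a and Pnp families and of ribosomal protein genes with pseudogene copies are uncertain. The labels and notes used here do not state whether counting used strand.

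Library totals ran from 58 to 5309505 counts. Libraries with at least 100000 counts entered the tests of expression, 12 WT and 17 K49A. Genes were kept with filterByExpr, which left 12456, and library sizes were scaled with TMM. The groups were compared with the quasi-likelihood test of edgeR 4.0.16 (robust, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic. CPM are counts per 1000000 after this scaling. Positions come from GENCODE M21 on GRCm38, in which 12433 of the 12456 tested genes were found.

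Of 22 gene lists, 21 had at least 5 tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The list of Y-linked genes had 0 tested members. A score is the mean of log2(CPM + 1) over the tested members of a list in an embryo. Scores, distances between embryos and detected genes were compared by 2-sided permutation tests with 100000 resamples. Numbers of libraries were compared with Fisher's exact test, 2-sided, and intervals of shares are exact 95% binomial intervals that cover counting error only.

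The genes named are up to 12 calls in each direction that have the largest fold change, a standard symbol and a mean of at least 10 CPM. Where fewer than 12 were called, all of them are named, filled up to 6 by the genes with the smallest p, with values only. To these were added up to 4 members of each list with the smallest p, and Prm1 and Prm2. Of the genes this rule names, 1 is not reported here. Nat8l, Lhfpl5, Gm12463 and Rps2-ps13 were named after their values were seen. This rule, the lists, the tests and most alternatives were fixed before the data were examined. The alternatives covered normalization, the test, filters, depth, left-out embryos and the replicate number as a block. Alternatives added later were the restriction to libraries with at least 1000000 counts and 12000 detected genes, plate column as a factor, the activation score as a covariate, and the embryos whose numbers occur in both groups without the block. The first of these kept 10 WT and 14 K49A embryos, called deep libraries below.

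A deposited table gives the row and column of each well. WT embryos filled rows 1 to 4 and K49A embryos rows 5 to 8, so plate row and group cannot be told apart, while columns 1 to 6 held both groups. The closest pair of libraries, K49A replicates 17 and 18, had a Spearman correlation of 0.915. They differed far beyond sampling noise, with a chi-square statistic 20.1 times its degrees of freedom, so no library was counted as a repeat of another. The statistic is set against count sampling alone, so it cannot exclude wells that share material.

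The test was tested on simulated data with the depths and spread of these libraries and 200 changed genes. Among 50 genes per size, it recovered 1 at 2-fold, 22 at 4-fold, 36 at 8-fold and 40 at 16-fold, with 1 false call among 11848 genes. Differences of up to about 4-fold in single genes were therefore mostly out of reach. Genes were simulated independently of each other, without the correlation between genes in the real libraries. The single false call therefore does not give the error rate on these data. Recovery can also be lower on real data where fewer than 200 genes change.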

Results

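The data set measured polyadenylated RNA in 48 single 2-cell mouse embryos, 24 WT and 24 K49A, and the comparison asks whether transcript levels at this stage differ when protamine 1 carries the K49A substitution. Depth differed widely between wells. At least 100000 counts were reached by 12 of 24 WT libraries (50%, 95% interval 29.1 to 70.9) and by 17 of 24 K49A libraries (70.8%, 48.9 to 87.4), which is no detectable difference (odds ratio 2.38, Fisher's exact p = 0.238). The tested WT libraries held 421301 to 5309505 counts (median 3787500) and the tested K49A libraries 105627 to 4947276 (median 4034654). The 19 libraries below the minimum held at most 39135 counts. Plate column 1 gave 1 tested library of 8 and column 2 gave 4 of 8, against 6 of 8 in each of columns 3 to 6. Plate rows were uneven too. Rows 1 to 4, all WT, gave 1, 4, 1 and 6 tested libraries of 6. Rows 5 to 8, all K49A, gave 4, 5, 5 and 3 of 6. Fisher's exact test treats wells as independent, while low depth was spread unevenly over rows and columns.

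**Figure D1:**
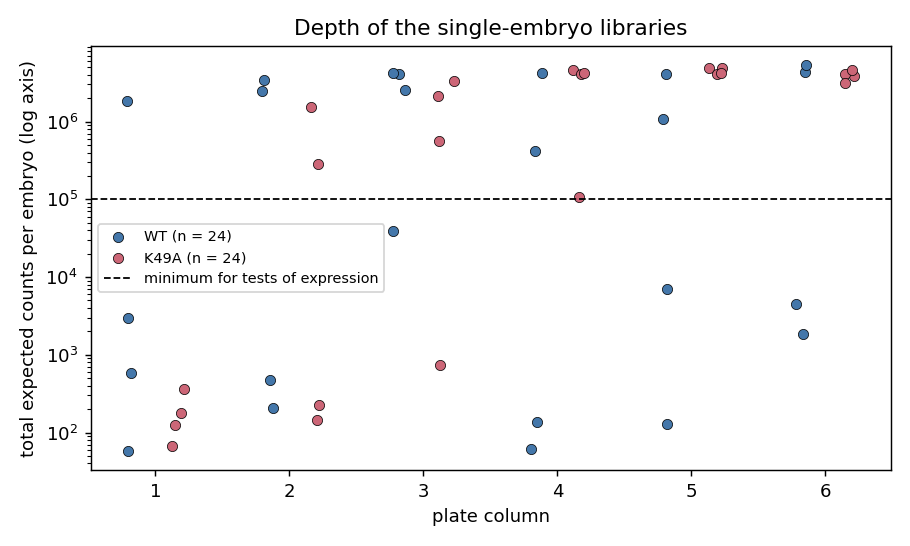
Total expected counts per embryo (log axis) by plate column, 1 point per library, with the minimum of 100000 counts as a dashed line. Only 1 of the 8 libraries in column 1 lies above the line.

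Transcripts of the protamines were scarce in both groups. Prm1, the gene named in the study's title, had at most 2 counts in any of the 12 tested WT embryos and at most 3 in any of the 17 K49A embryos, with a count in 2 and 4 embryos. Counts per gene do not show a substitution of 1 amino acid, so Prm1 transcript does not check the genotype labels. Prm2, which encodes the other main sperm protamine, was counted in 12 of 12 WT and 16 of 17 K49A embryos, with medians of 10.5 and 9 counts. Its log2 fold change was 1.76 ± 0.93 (SE, adjusted p = 0.689 in edgeR's quasi-likelihood test), and the sign turned in the deep libraries, where it was -0.68. Among 9 tested members of the spermatid and sperm list (median 0.16, camera adjusted p = 0.947), 0 passed the threshold, over all genes or adjusted over the list alone.

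K49A embryos had lower levels of Extl1 and Bcat2, and these 2 genes were the only calls among the 12456 tested. Bcat2 encodes the mitochondrial branched-chain aminotransferase and lies on chromosome 7 from 45570153 to 45589711 (plus strand, GRCm38). It averaged 134 CPM ± 126 (SD, n = 12) in WT and 7.21 CPM ± 6.68 (n = 17) in K49A embryos. Its log2 fold change was -4.12 ± 0.64 (SE, adjusted p = 0.00163, edgeR). The WT embryos were not uniform: 8 lay above the highest K49A embryo (26.4 CPM) and 4 lay within the K49A range. The 4 were replicates 5, 9, 10 and 15, all in plate rows 1 to 3 (0 to 6.48 CPM). Replicates 8 and 12 in row 2 held 158 and 123 CPM, and replicates 19 to 24 in row 4 held 80.7 to 398 CPM. Whether Bcat2 depends on row within WT was not tested, and neither plate columns nor single left-out embryos can show it. Extl1, an exostosin-like glycosyltransferase gene, lies on chromosome 4 from 134356372 to 134383850 (minus strand). It averaged 40.5 CPM ± 39.4 in WT and 1.71 CPM ± 2.47 in K49A, a log2 fold change of -4.44 ± 0.71 (adjusted p = 0.00163). All 17 K49A embryos lay below the WT median for both genes, and 10 of 12 WT embryos exceeded every K49A embryo for Extl1. Within plate columns 2 to 6, the difference in mean log2(CPM + 1) was negative in each column, from -5.68 to -0.50 for Bcat2 and from -5.13 to -2.52 for Extl1. Both calls were also made after each of the 29 embryos was left out in turn. Among the embryos whose replicate number occurs in both groups, Bcat2 was not called: its log2 fold change was -2.79 (adjusted p = 0.373), and -1.62 (adjusted p = 1.0) with the number as a block. Extl1 was at -4.82 (adjusted p = 0.0508) and, with the block, at -5.95 (adjusted p = 0.0108). The embryos with shared numbers leave out WT replicates 19, 20 and 21, which held the highest Bcat2 levels (398, 245 and 276 CPM). They keep the 4 WT embryos within the K49A range for Bcat2, so the Bcat2 difference depended on which WT embryos entered.

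No gene was called higher in K49A by edgeR, although 963 genes had an unadjusted p under 0.05, 778 of them higher and 185 lower, against 623 expected by chance. In the deep libraries 653 of 12834 genes had such a p, against 642 expected. DESeq2 called 75 higher and 12 lower, and limma with quality weights 26 higher and 14 lower. Single embryos decided some further calls. Leaving out WT replicate 9, 10 or 15 gave 4 lower genes, with Pnp and the pseudogene Rps2-ps13 added. Leaving out WT replicate 8 or 22 gave 3, with Rps2-ps13, and leaving out K49A replicate 16 gave 3, with Pnp. S100a10 was called higher without WT replicate 9 or without K49A replicate 4, 5, 8, 11 or 16. Nat8l was called higher without WT replicate 9, 10, 12 or 15, and Lhfpl5 without WT replicate 12, so the count of higher genes ran from 0 to 2.

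Below the threshold, the 6 genes with the smallest p among those higher in K49A, with a standard symbol and a mean of at least 10 CPM, were S100a10, Uqcr11, Lgals1, Rps28, Cox6a1 and Atox1. S100a10, whose product binds annexin A2, averaged 0.804 CPM ± 1.09 in WT and 23.3 CPM ± 58.6 in K49A (log2 fold change 4.57 ± 0.92, adjusted p = 0.0652, edgeR), and 11 of 17 K49A embryos exceeded every WT embryo. K49A replicate 3, one of the shallow libraries, held 248 CPM against a K49A median of 6.997, and the log2 fold change of S100a10 was 2.68 in the deep libraries (adjusted p = 0.575, from 0.00101 to 0.575 over all alternatives). Lgals1, a galectin gene, had a log2 fold change of 3.17 ± 0.77 (adjusted p = 0.213). Lgals1 was called higher with plate column as a factor, with DESeq2 and without a low-count filter. Cox6a1 and Uqcr11 encode subunits of the respiratory chain, with log2 fold changes of 2.63 ± 0.65 and 3.98 ± 0.91. Values for the ribosomal protein gene Rps28 and the copper chaperone gene Atox1 were 3.55 ± 0.86 and 2.86 ± 0.71. A few K49A embryos outside the deep libraries carried much of these values. Rps28 reached 5138 CPM in K49A replicate 22 and 1616 in replicate 14, while the medians were 43.5 CPM in K49A and 35.8 in WT. Cox6a1 reached 2792 CPM in replicate 14 and 2767 in replicate 3 (medians 97.0 and 68.2), and Atox1 reached 1354 in both (medians 38.6 and 28.0). In the deep libraries the log2 fold change of Uqcr11 was 1.88, the log2 fold change of Lgals1 2.13, the log2 fold change of Rps28 0.97, the log2 fold change of Cox6a1 1.21 and the log2 fold change of Atox1 0.74. Among genes lower in K49A, Pnp, which encodes purine nucleoside phosphorylase, averaged 207 CPM ± 124 in WT and 64.9 CPM ± 43.3 in K49A (-1.66 ± 0.35, adjusted p = 0.0827). All 17 K49A embryos lay below its WT median. The log2 fold change of Pnp was -1.88 without K49A replicate 16 (adjusted p = 0.00716), and its adjusted p over all alternatives ran from 0.00101 to 1.0. Pnp has a near-identical neighbour, Pnp2, so the division of reads between them is uncertain. Aunip, which lies 155 kb from Extl1, and Ercc4 had log2 fold changes of -1.27 ± 0.35 and -1.67 ± 0.46, both with an adjusted p of 0.308.

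**Figure D2:**
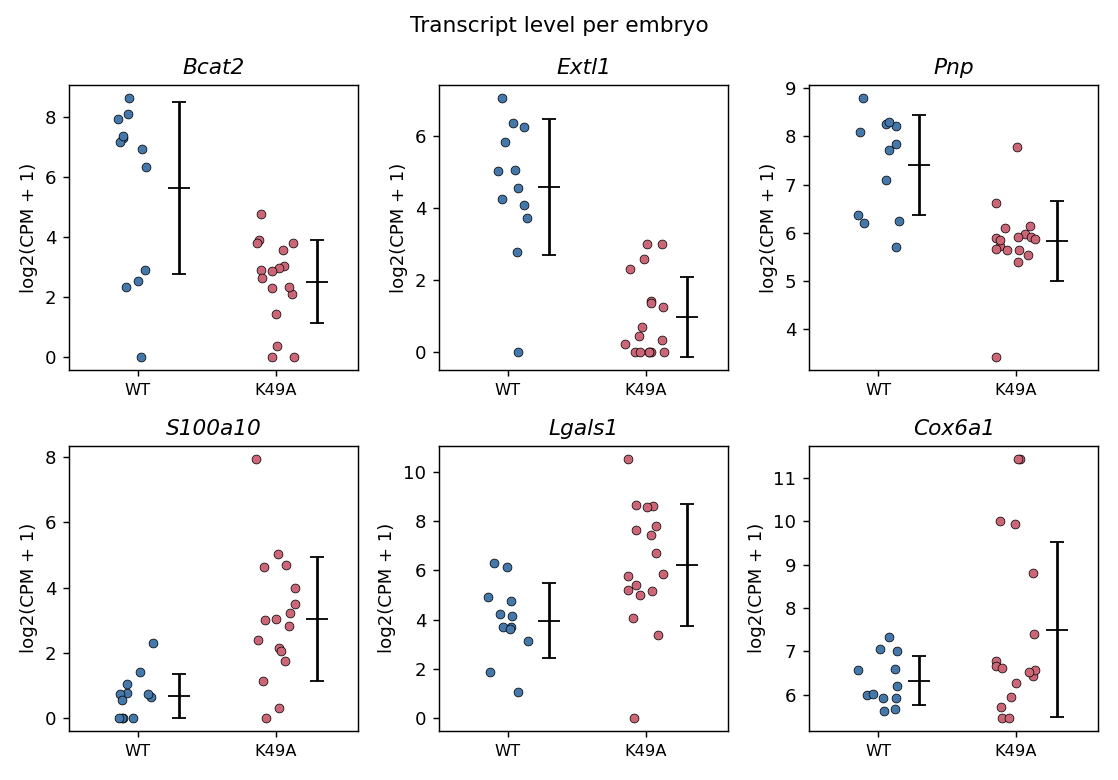
Level of 6 genes per embryo as log2(CPM + 1), 1 point per embryo in 12 WT and 17 K49A embryos, with the mean and SD as bars. For Bcat2, 8 WT embryos lie above all K49A embryos and 4 lie among them.

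The list of 2-cell activation genes, transcribed when the embryonic genome switches on, had 29 of 41 tested members with a negative fold change and a median log2 fold change of -0.28. No member passed the threshold over all genes, and 0 did when adjusted over the list alone. Camera placed the list lower at the preset correlation (adjusted p = 9.04e-07), but not with an estimated correlation (adjusted p = 0.622), nor did fry (adjusted p = 0.846). Its members with the smallest p were the transcription factor gene Spz1 (-1.40 ± 0.44) and the near-identical copies Zscan4c (-1.45 ± 0.62) and Zscan4d (-1.43 ± 0.65), markers of the 2-cell stage. The activation score averaged 5.35 ± 1.25 (SD, n = 12) in WT and 4.74 ± 1.49 (n = 17) in K49A. The difference of -0.61 (95% bootstrap interval -1.57 to 0.35) did not exceed the spread between embryos (permutation p = 0.256). Within plate columns 2, 3, 4, 5 and 6 it was -1.32, -0.66, -1.06, 0.02 and -1.34.

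The level of oocyte transcripts carried over from the egg, taken as a score, did not differ detectably. The maternal score averaged 6.72 ± 0.57 in WT and 6.64 ± 0.62 in K49A, a difference of -0.08 (95% bootstrap interval -0.51 to 0.33, permutation p = 0.729), and its sign differed between plate columns, from -1.25 to 0.76. Of 80 tested members, 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.0657). With the replicate block camera placed this list lower (adjusted p = 0.00208, preset correlation). Without the block, camera with an estimated correlation gave no call (adjusted p = 0.954). Sohlh1 and Ooep, genes of the oocyte programme, had log2 fold changes of 2.21 ± 0.75 and 1.06 ± 0.47, and Tcl1b4 -0.73 ± 0.40. The machinery that degrades maternal RNA (45 members, median -0.07, camera adjusted p = 0.482) also had 0 members past the threshold. The activation and maternal scores were not related across the 29 embryos (r = 0.06, permutation p = 0.751; rho = -0.04, p = 0.854). Without the 2 embryos farthest from the median activation score r was 0.16, within WT -0.14 and within K49A 0.15. In plate columns 3, 4, 5 and 6, with 6 embryos each, r was 0.34, 0.13, 0.92 and -0.74. In the 24 deep libraries the activation and maternal score correlation was -0.47 (permutation p = 0.0192).

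**Figure D3:**
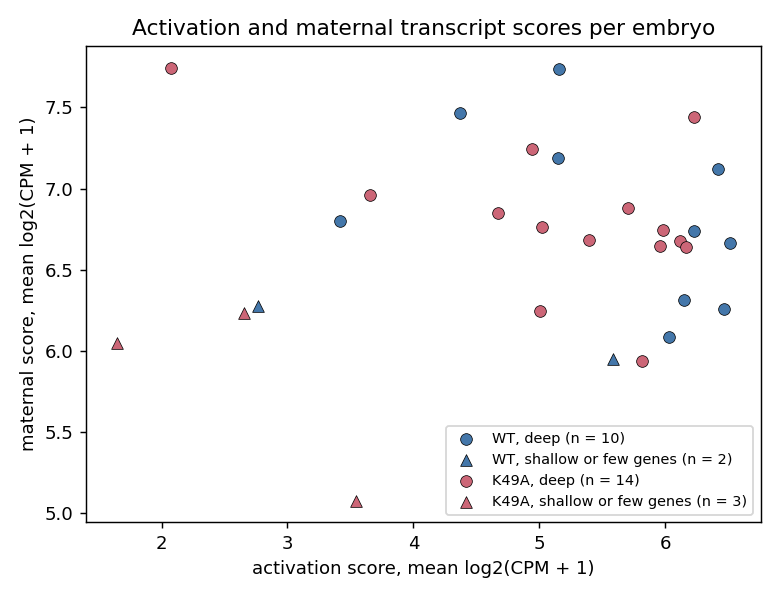
Activation score against maternal score, both as mean log2(CPM + 1), 1 point per embryo, with triangles for the 2 WT and 3 K49A embryos outside the deep libraries. The activation score spans 1.65 to 6.51 and overlaps between the groups.

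Nuclear genes of oxidative phosphorylation, which encode the respiratory chain and ATP synthase, had 64 of 72 tested members with a positive fold change and a median log2 fold change of 1.36. None passed over all genes, and 33 were higher when adjusted over the list alone. Camera placed the list higher (adjusted p = 0.0016), but not with an estimated correlation (adjusted p = 0.847). Ndufa11 and Ndufa4, both of the respiratory chain, had log2 fold changes of 2.40 ± 0.62 and 2.12 ± 0.61. The score of this list averaged 4.37 ± 0.66 in WT and 5.06 ± 1.03 in K49A (permutation p = 0.0531, adjusted p = 0.558 over 21 lists). It was 6.92 in K49A replicate 3, 6.94 in replicate 14 and 6.41 in replicate 22, the 3 K49A embryos outside the deep libraries. High scores were not confined to them: K49A replicates 8 and 15, both deep, had 6.30 and 6.05. WT replicates 10 and 5, the 2 WT embryos outside the deep libraries, had 3.28 and 5.24. The median fold change in the deep libraries was 0.42. Ribosomal protein genes behaved alike in the counts of members: 77 of 80 were positive (median 1.53), 0 passed over all genes and 41 were higher adjusted over the list alone. Camera gave no call for them (adjusted p = 0.601), but placed them higher with plate column as a factor (adjusted p = 1.53e-09) and with the replicate block (2.40e-16), both at the preset correlation, while the estimated one over all tested libraries was 0.72 (adjusted p = 0.955), and gave no call in the deep libraries (0.787). Rplp1 and Rpl34 had log2 fold changes of 2.92 ± 0.78 and 2.73 ± 0.72, and the list median in the deep libraries was 0.60. The 15 transcripts encoded by mitochondrial DNA had a median of 0.08 and 0 members past the threshold (camera adjusted p = 0.482), but were placed lower in the deep libraries (median -0.24, adjusted p = 1.54e-04 at the preset correlation and 0.642 with an estimated one) and at a minimum of 500000 counts (0.0235), and higher with the replicate block (0.0224), so no direction is given for them.

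Genes of the cell cycle had 45 of 60 members with a negative fold change (median -0.29), with 0 past the threshold over all genes or adjusted over the list alone. The camera call (adjusted p = 1.73e-05) was lost with an estimated correlation (adjusted p = 0.622). Aurka, a mitotic kinase gene, and Mcm4, a subunit of the replicative helicase, had log2 fold changes of -1.10 ± 0.46 and -1.18 ± 0.46, while Cdk4 was at 1.18 ± 0.42. Genes that remodel paternal chromatin after fertilization had a median of -0.13, with 48 of 75 negative. That call (adjusted p = 0.0065) was lost too (adjusted p = 0.622 with an estimated correlation). Its members included Kdm4a (-0.76 ± 0.34), Nap1l1 (-0.46 ± 0.24), Ssrp1 (-0.51 ± 0.27) and Dnmt3a (0.85 ± 0.38), and 0 passed over all genes or adjusted over the list alone. Splicing factors (55 members, median 0.01, mean 0.17) and ribosome biogenesis genes (73 members, median -0.06, mean 0.03) were placed lower by camera (adjusted p = 0.0142 and 0.0393), against the sign of the mean in both. With an estimated correlation the adjusted p were 0.622 and 0.954, and 0 members passed by either count.

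Maternally expressed imprinted genes had 18 of 23 members with a positive fold change (median 0.38, camera adjusted p = 0.0393, and 0.622 with an estimated correlation). Meg3 was at 1.16 ± 0.46 and Cdkn1c at 1.27 ± 0.66, with 0 members past the threshold by either count. Paternally expressed imprinted genes (17 members, median 0.03, camera adjusted p = 0.601) included Plagl1 at 2.36 ± 0.76 and Kcnq1ot1 at -1.26 ± 0.65. DNA repair (86 members, median 0.01, adjusted p = 0.589), p53 response (41, median 0.09, 0.806), heat shock and stress (43, median 0.14, 0.601), proteasome (37, median 0.11, 0.947) and X-linked genes (16, median 0.08, 0.947) gave no call. In each of these lists, and among the paternally expressed genes, 0 members passed over all genes or adjusted over the list alone. Cdkn1a, a p53 target that halts the cell cycle, had a log2 fold change of 1.05 ± 0.48 (adjusted p = 0.564). Among the DNA repair genes, the nuclease gene Ercc4 is given above. Rad51d, Polm and Atrip, of the same list, had positive log2 fold changes of 1.57 ± 0.54, 0.93 ± 0.35 and 1.14 ± 0.56.

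Markers of cumulus and blood cells had mostly positive fold changes, while the median over all tested genes was also positive (0.11). Most of these markers did not pass the low-count filter: 10 of 36 cumulus and granulosa markers and 6 of 19 blood cell markers were tested. Of 10 tested cumulus and granulosa markers, 9 had a positive fold change (median 0.59), 0 passed over all genes and 2 were higher adjusted over the list alone, Kitl (2.08 ± 0.67) and Sparc (2.36 ± 0.82). Kitl was scarce, with means of 0.987 CPM in WT and 4.21 CPM in K49A. Camera gave an adjusted p of 0.0393, and 0.622 with an estimated correlation. Among 6 blood cell markers, 5 were positive (median 1.76), 0 passed over all genes and 4 were higher adjusted over the list alone: Cd74 (3.03 ± 0.79), the haemoglobin copies Hba-a1 (2.67 ± 0.80) and Hba-a2 (2.07 ± 0.87), and Laptm5 (1.45 ± 0.53). Group medians of the haemoglobin copies lay closer: 6.75 CPM in WT and 8.77 in K49A for Hba-a1, and 4.36 and 5.04 for Hba-a2. The camera adjusted p was 0.289, and 0.0119 (higher) with the replicate block, both at the preset correlation. Without the block, an estimated correlation gave 0.732. Of 39 markers of later preimplantation stages, 21 had a positive fold change, 0 passed over all genes and 1, Lgals1, was higher adjusted over the list alone (median 0.05, camera adjusted p = 0.41). Camera pointed lower against a positive median and mean for later preimplantation markers, DNA repair, paternally expressed imprinted genes, mitochondrial transcripts and the spermatid list, none of them called. For the maternal list and the decay machinery a negative median stood beside a mean of 0.0042 and 0.0085. Over all 21 lists, fry gave no call (smallest adjusted p = 0.226).

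**Figure D4:**
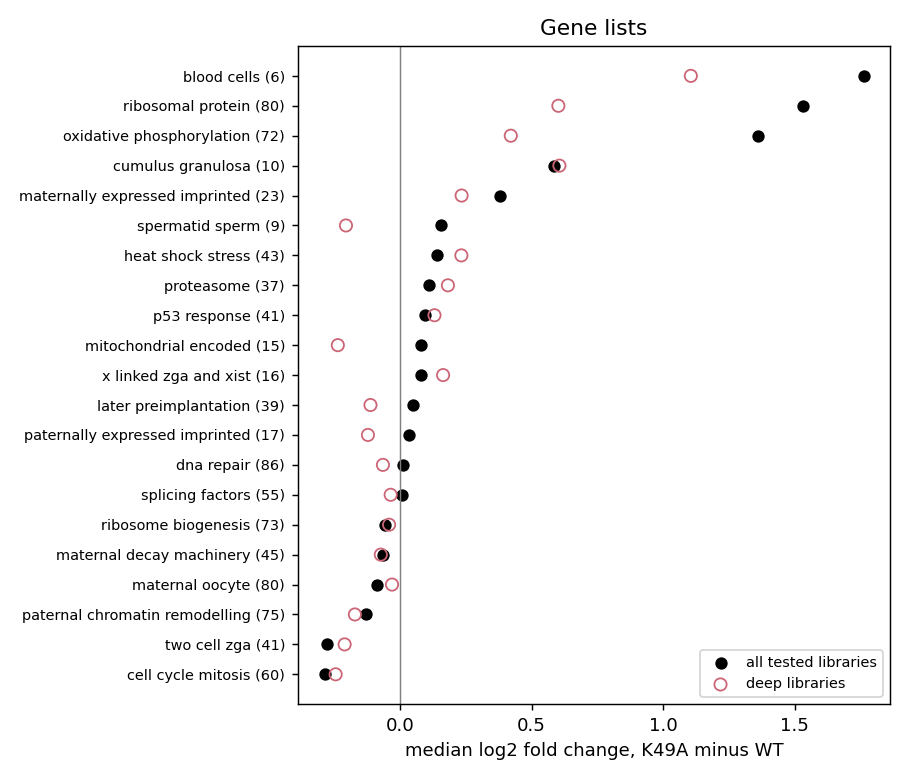
Median log2 fold change (K49A minus WT) of each gene list, with the number of tested members, over all 29 tested libraries (black) and over the 24 deep libraries (open red). Oxidative phosphorylation lies at 1.36 over all libraries and at 0.42 over the deep ones.

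Embryos within a group were about equally unlike. The mean distance between embryos, 1 minus the Spearman correlation, was 0.34 in K49A and 0.294 in WT, a difference of 0.0456 (permutation p = 0.455). After thinning to 100000 counts, 3464 ± 387 genes (SD, n = 12) reached 5 counts in WT and 3402 ± 599 (n = 17) in K49A, a difference of -62.1 (95% bootstrap interval -404 to 288, permutation p = 0.754). The direction depended on the minimum and the depth: the detected genes difference was 457 at 1 count and 302 after thinning to 300000 counts, neither past the threshold (permutation p = 0.31 and 0.336). Without thinning the means were 12523 and 12593. The first principal component (27% of variance) followed depth (rho = 0.82, p = 1e-05, the smallest that the permutations can give) and showed no detectable difference between groups (permutation p = 0.887). The third component (9.80% of variance) differed between groups at an unadjusted permutation p of 0.0306, not adjusted for the 4 components tested, and was related to the activation score (rho = -0.57, p = 0.00168). The first component was related to that score as well (rho = 0.65, p = 1.80e-04).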

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

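All 19 libraries below 100000 counts, which the main comparisons of expression do not use (WT replicate 3 enters the alternative with a minimum of 10000 counts), held transcripts of the oocyte list above the share that a count of 0 would allow. The limit is 3 counts over the library total, so any library with more list counts passes it, and it shows only that such transcripts are present. The shares are values of single libraries, and no explanation was tested. WT replicate 3, with 39135 counts, had 3.88% of its counts in the list, against a limit of 0.00767%. Shares in the other WT libraries were 17.6% in replicate 11, 8.96% in replicate 6, 4.81% in replicate 7, 1.09% in replicate 18, 5.41% in replicate 1, 10.04% in replicate 2, 5.71% in replicate 14, 4.44% in replicate 16, 5.43% in replicate 17, 6.45% in replicate 4 and 8.62% in replicate 13. In K49A libraries they were 3.14% in replicate 21, 8.82% in replicate 1, 2.65% in replicate 2, 8.52% in replicate 13, 6.21% in replicate 20, 3.97% in replicate 19 and 7.35% in replicate 7. The 29 tested libraries had 3.01 to 18.3%, with a median of 8.20%. The lowest of the shallow libraries held 58 counts, where 5 counts make up the share.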

How the results depend on the processing

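Added after the data were examined were the deep libraries, plate column, the activation covariate and the shared numbers without a block. Higher and lower genes numbered 75 and 12 with DESeq2, 26 and 14 with limma, and 661 and 465 without a low-count filter, which tests 30892 genes. A filter of 10 counts in 80% of libraries gave 0 lower genes and thinning 1, and both left Bcat2 and Extl1 untested. The deep libraries gave 4 lower genes, with Gm12463 and Rps2-ps13 added. There was 1 higher gene at a minimum of 10000 counts (S100a10), 2 with plate column (S100a10 and Lgals1) and 1 with the activation covariate (Lhfpl5). Over left-out embryos the counts ran from 0 to 2 higher and 2 to 4 lower. The replicate numbers did not pair the embryos: 2 of 9 pairs correlated above 0.1, and 0 of the 9 embryos correlated best with its own number. As a block they left 1 lower gene, Extl1 (Bcat2 at -1.62), with 0 among the same embryos without the block (Bcat2 at -2.79). Fewer embryos enter both fits, and the WT embryos left out, replicates 19, 20 and 21, held the highest Bcat2 levels. Of 8 list calls with the block, 4 were also made without it over all embryos. List calls fell from 8 to 0 with an estimated correlation, with fry, and in the deep libraries with an estimated correlation.

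The maternal difference became 0.13 at 10000 counts and 0.023 at 500000, and ranged from -0.15 to 0.018 over left-out embryos, turning sign without WT replicate 20 or K49A replicate 14. The activation difference ranged from -0.85 to -0.42 and the distance difference from 0.0239 to 0.078. The detected genes difference was 457 at 1 count and 302 after thinning to 300000, which keeps 12 WT and 15 K49A embryos. The activation and maternal score correlation turned to -0.30 at 500000 counts and -0.47 in the deep libraries (unadjusted p = 0.0192). Among named genes, the sign turned for the log2 fold change of Prm2 (-0.61 with limma, -0.56 with the block, -0.069 with the depth covariate, -0.68 in the deep libraries, -0.18 with the activation covariate), mt-Nd3 (-0.050 with limma, -0.33 in the deep libraries), mt-Atp6 (0.14 with the block, 0.24 without it), Hspa1l (0.67 with limma, 1.32 with the block) and, with limma, mt-Rnr1 (-0.15), Rpl37 (-0.23), Nop10 (-0.11), Snrpf (-0.21), Lsm7 (-0.10) and Atp7a (-0.090). Where not stated, the cause was not tested.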

Other observations

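The tests of a haplotype, with the bound that judged them, were chosen after the shares had been seen, and deep libraries, plate column and the relations of list scores were also taken up after the data were examined. The bounds of the other tests of explanations were set before those tests were run. Those on Bcat2, Extl1 and the oxidative phosphorylation and activation lists name results of the main comparison, so they were chosen after it. The windows around Bcat2, Extl1 and Pnp also follow genes named from that comparison. The activation score was positively related, past the adjusted threshold, to 14 of 20 other lists by r and 7 by rho over all tested libraries, but to 5 by r and 3 by rho in the deep libraries. Cell cycle and ribosome biogenesis had the highest r. Across the 29 embryos the activation score correlated with the cell cycle score (r = 0.86, rho = 0.86, permutation p = 1e-05 for both, the smallest possible, adjusted p = 1e-04 and 2e-04 over 20 relations) and with ribosome biogenesis (r = 0.81, rho = 0.72, adjusted p = 1e-04 and 2.67e-04). In the 24 deep libraries r was 0.78 and 0.74. Among these, without the 2 embryos farthest from the median it was 0.78 and 0.63, within WT 0.81 and 0.71, and within K49A 0.76 and 0.76. Over all tested libraries, in plate columns 3, 4, 5 and 6 with 6 embryos each, r was 0.94, 0.83, 0.25 and 0.92 for the cell cycle and 0.88, 0.87, -0.42 and 0.84 for ribosome biogenesis, so column 5 did not show it, and columns 1 and 2 held too few. Other lists had r of 0.71 (DNA repair), 0.70 (p53 response), 0.68 (heat shock and stress), 0.64 (splicing) and 0.64 (X-linked), so the relation was not particular to those named first. In the deep libraries r was 0.60 for DNA repair (adjusted p = 0.012), 0.60 for p53 response (0.017), 0.54 for splicing (0.0239), 0.48 for heat shock and stress (0.063) and 0.12 for X-linked genes (0.673). Without the 2 farthest embryos the p53 value was 0.097 and the heat shock value -0.0072, so these rest on those embryos. By rho, p53 response (adjusted p = 0.438) and splicing (0.115) were not past the threshold. With scores scaled over all 29 libraries, the maternal score in the deep libraries had r = -0.48, rho = -0.45 and adjusted p of 0.0598 and 0.115.

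Y-linked transcripts reached 20 counts in 5 of 12 WT and 4 of 17 K49A embryos (Fisher's exact p = 0.422). Within 2 Mb of Prm1 on chromosome 16, 1 of 19 tested genes had an unadjusted p under 0.05 (5.26%), against 7.73% of all tested genes. The same window held 5 of 82 genes around Bcat2 (6.10%), 6 of 76 around Extl1 (7.89%) and 4 of 25 around Pnp (16%).

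The number of genes and lists called was set beside other splits of the 29 embryos into groups of 12 and 17. In 6 of 100 splits, the real one included, 2 or more genes were lower, so chance could not be excluded for that count. The highest other split gave 847 lower genes, and a split that calls several times the real count points to a structure of the samples other than group. For higher genes the real count was 0, so all 100 of 100 splits had to give as many and this count decides nothing (highest other 257). The 8 list calls at the preset correlation were matched in 12 of 100 splits, with up to 10 in another split, so chance could not be excluded for them either.

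Lower Bcat2 and Extl1 in K49A embryos do not rest on shallow libraries: in the deep libraries the log2 fold changes were -4.29 for Bcat2 and -4.17 for Extl1, both still past the threshold. For Bcat2 this check also leaves out WT replicates 10 and 5, at 4.83 and 0 CPM, which lay within the K49A range. The K49A embryos left out held 0 to 7.29 CPM. A chromosome haplotype that differs between embryos stays undecided as an explanation for Bcat2. Of the 50 genes most correlated with Bcat2 across embryos, 32% lay on its own chromosome 7 (exact 95% interval 19.5 to 46.7). Over all tested genes the median was 6% and the 95th percentile 20%, which the share exceeds and the interval just reaches. These chromosome 7 genes lay from 5.58 to 95.8 Mb away, and the interval treats correlated genes as independent. Within 2 Mb of Bcat2, 6.10% of genes had an unadjusted p under 0.05 (edgeR), against 7.73% of all tested genes. The labels give 1 strain for all embryos. The share therefore cannot tell a haplotype from other sources of shared variation. For Extl1 the share was 4.0% (exact 95% interval 0.488 to 13.7), which argues against a haplotype that moves many genes of chromosome 4 but leaves open a variant that acts on Extl1 or few genes near it. Aunip, 155 kb away, had a log2 fold change of -1.27 (edgeR, unadjusted p = 7.71e-04, adjusted p = 0.308). Whether Aunip and Extl1 share a cause was not tested. The substitution, the parents, and plate row, which follows the groups, stay open.

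The oxidative phosphorylation list was, of the list tests, placed higher only by camera at the preset correlation, and not with an estimated correlation (adjusted p = 0.847) or by fry. Its positive median may come partly from transcript length or from shallow libraries. Members had a median transcript length of 751 bases, against 2465 over all genes, and subtraction of the trend with length took the median log2 fold change from 1.36 to 0.82. In the deep libraries it was 0.42. Both values lie between the bounds set for presence and absence of an effect, so neither explanation can be told apart from an effect of group.

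The 2-cell activation list was placed lower only by camera at the preset correlation (adjusted p = 0.622 with an estimated correlation), and its score difference did not exceed the spread between embryos (permutation p = 0.256). That difference was -0.42 in the deep libraries and -0.84 (SE 0.46) with plate column as a factor, against -0.61 without. The first lies between the bounds set, so shallow libraries cannot be told apart from group here. Plate columns 2 to 6 held both groups, and adjustment for column did not shrink the difference. The adjusted difference passed its bound by less than its error, so its size within columns stays uncertain. A difference in pace of development between 26 and 28 hours could not be tested, since the labels give 1 window for all embryos.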
